A study of Rattus norvegicus with 6 samples.

How the data were processed

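Total RNA from left ventricular myocardium of 6 male Wistar rat samples, 3 on normal chow and 3 on a high-fat diet for 20 weeks, was labelled with cyanine 3 and hybridized to Agilent rat miRNA arrays in 1 colour, per the labels' protocols. The spot intensity values were deposited by the authors as scanner output of Agilent Feature Extraction 11.0.1.1, per the file headers and the submitters' processing notes, with 1 array per sample and no pooling. These intensities are linear, background-subtracted and not normalized between arrays, and reached from -7.93 to 379400 over all spots, control spots included. Flags for detection, saturation, outlier spots and control spots came from the same files. No miRNA spot was flagged as saturated. The authors also deposited a value table of the whole series on the log2 scale. Its software is not given in the sources used here. Set against the scanner files, each column followed the rank order of Agilent's total signal per miRNA (Spearman's rho of 1.00 in each column, rounded) and all 6 columns held the same median of 3.54 and 75th percentile of 6.62, the pattern that quantile normalization gives. That table covers 780 features, control features included, and its direction and scale were taken from this comparison. The header of the array grid names the rat genome build rn4. No coordinates of that build were used.

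Control spots and spots flagged as non-uniform or population outliers were left out, and the remaining spots of each probe were averaged on the linear scale. A probe counted as detected on an array when more than 0.5 of its spots were well above background, and a miRNA when at least 1 of its probes was. Each array was divided by its 75th percentile over the 746 probes detected on all 6 arrays and brought back to a common level. The 75th percentiles were 361.2, 450.5 and 384.3 on normal chow and 426.4, 539.6 and 576.6 on the high-fat diet (replicates 1, 2 and 3). Values under 10.8, the median over arrays of the lowest scaled signal among detected probes, were set to that floor. Probes of one miRNA were summed and the sum taken to log2. The 408 miRNAs detected on all 3 arrays of at least 1 diet were tested, of which 375 were detected on all 6 arrays. Of the 758 miRNAs, 284 were detected on no array. Probes of the same miRNA moved alike, since over the 313 miRNAs with at least 2 detected probes the median range of their log2 fold changes was 0.05 and 0 miRNAs had a range over 0.5. No pair of arrays held identical spot values. Names are those of the array design without their species prefix.

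The diets were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over the tested miRNAs and a threshold of 0.05. A fold limit of 1.5 with an unadjusted p under 0.05 was counted as a description. The number of arrays limits the precision, and the median SE of a log2 fold change was 0.11. Numbers of detected miRNAs were compared with an exact permutation test. Before the data were examined, 22 lists of miRNAs were fixed for heart muscle, fibrosis, hypertrophy, metabolism, other cell types, blood, families and gene clusters, with 177 entries, of which 176 were on the array. The entry absent under the fixed names was miR-378a-3p, which is not analysed here. Lists of at least 3 tested members, 21 of the 22, were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. With an estimated correlation 0 lists passed, and with fry, which tests whether a list's members move one way on balance, 0 lists passed. With an estimated correlation camera also refers its statistic to the few residual degrees of freedom of the arrays. A list can therefore fail that test without any correlation among its members. The lists share some members, such as 3 of the 9 muscle entries and 1 of the 8 epithelial entries, and 0 of the 4 erythroid entries. Of these lists, 9 muscle, 4 erythroid and 2 epithelial members were detected on all normal chow arrays. For a miRNA not detected on any array of 1 diet, a ratio set the floored mean of the other diet against a limit. The limit was, per array, the higher of that array's lowest detected signal and the miRNA's own. The floor can raise this ratio, so it is not a lower bound.

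The miRNAs named in the text were chosen by a rule fixed before the data were examined. It took every miRNA past the threshold, those of smallest unadjusted p until 24 were named, up to 4 of the brightest tested members of each list, the 5 brightest miRNAs, 8 fixed heart, fibroblast, blood and liver miRNAs, and those detected on all arrays of one diet and none of the other. Further list members (miR-206-3p, miR-486, miR-33-5p, and the untested miR-200a-3p, miR-200b-3p, miR-429 and miR-205) were chosen after their values were seen. The steps were tested on simulated arrays with the means and moderated residual spreads of the 408 miRNAs. These spreads, as shrunk by limma, vary less between miRNAs than the observed ones. In each of 50 simulations of this comparison 60 of the miRNAs were changed. Of the changed miRNAs, 78.5% were called at a log2 change of 0.5, 98.4% at 1 and 99.7% at 1.5, and 0.8% of the unchanged ones were called. A muscle list shifted by -0.25 was called in 98% of simulations and unshifted lists in 0.4%. These simulations changed more miRNAs than were called here, drew independent miRNAs from the shrunken spreads, and applied no floor or scaling. The shares of changes recovered are therefore upper ones for a single changed miRNA and for correlated lists. The share of unshifted lists called is a lower one for correlated lists.

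The alternatives changed the background correction, the scaling, the summary of probes, the filter on dim miRNAs, the floor, the moderation, array weights, the replicate number as a block, the input values and the arrays included. Normexp was planned on mean spot signals, but the files hold no mean signal under the planned name. It was run instead with an offset of 50 on the median spot and background signals. This offset adds to every spot, so it shrinks the log2 fold changes of dim miRNAs by construction. All 6 arrays carry the same scan identifier and scan date, so slide and scan date could not be used as batches. Slide barcodes are not given in the sources used here. The slide row was read as the first part of each array's position label, which places normal chow replicate 1 and all 3 high-fat arrays in slide row 1 and normal chow replicates 2 and 3 in slide row 2. Fits with the slide row as a block, with slide row 1 alone, and with the array's brightness (log2 of its 75th percentile) as a covariate were added after the data were seen. Neighbouring miRNA genes were taken from a RefSeq gene table of assembly GRCr8 as genes within 10 kb of each other on a chromosome, with none of its coordinates printed, and 374 of the 408 tested miRNAs matched 1 gene. Figures were drawn with matplotlib 3.10.9.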

Results

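The question put by the series was whether a high-fat diet changes the microRNA (miRNA) content of the rat heart. Total RNA from left ventricular myocardium of male Wistar rats, an outbred laboratory stock, was hybridized to Agilent rat miRNA arrays in 1 colour after 20 weeks on normal chow (3 arrays) or on a high-fat diet (3 arrays). The arrays measured 758 rat miRNAs with 1806 probes. The 5 brightest miRNAs over the 6 arrays were miR-133b-3p, miR-1b, miR-1-3p, let-7a-5p and let-7f-5p, the first 3 of which belong to the muscle-enriched miR-1 and miR-133 families. The normal chow arrays detected 391, 413 and 383 miRNAs (replicates 1, 2 and 3), and the high-fat arrays detected 409, 448 and 468. The mean was 395.7 ± 15.5 on normal chow and 441.7 ± 30.0 on the high-fat diet (SD, n = 3 each), a difference of 46.0 with a two-sided exact permutation p = 0.2, where 0.1 is the smallest p that 3 against 3 arrays allow. The brightness of the detected probes moved the same way. The 75th percentile of their signal was 398.7 ± 46.3 on normal chow and 514.2 ± 78.3 on the high-fat diet (SD, n = 3 each, exact permutation p = 0.2). Each array was divided by its own 75th percentile before any comparison. Pearson's r between arrays, across miRNAs on the log2 scale, lay between 0.991 and 0.997. The most alike pair crossed the diets, normal chow replicate 3 with high-fat replicate 1 (r = 0.997, median absolute log2 difference 0.10). Slide row 1 held all 3 high-fat arrays and normal chow replicate 1, and row 2 the other normal chow arrays. A fit with the slide row as a block, or on row 1 alone, therefore sets normal chow replicate 1 against the high-fat arrays, with the spread of that lone array assumed to be that of the others, and cannot part the row from that array. The labels number the replicates within each diet and do not tie each number to an animal, so the p-values measure the spread between these samples.

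In hearts of rats on the high-fat diet, miR-224-3p fell by 1.06 on the log2 scale (SE 0.12, n = 3 per diet), a level 2.08-fold lower than on normal chow. It is the 3' arm of a miRNA whose gene lies in an intron of the GABA-A receptor subunit gene Gabre. Its 3 normal chow arrays read 6.56, 6.32 and 6.31 (log2 normalized signal) and its 3 high-fat arrays 5.56, 5.23 and 5.24. On the high-fat arrays miR-224-3p was dim, with probes at 4.17 to 4.68 (log2) against a floor of 3.43 per probe. It was the only one of the 408 tested miRNAs past the threshold (limma, adjusted p = 0.0209), so 0 miRNAs were called higher and 1 was called lower. At an unadjusted p under 0.05 there were 46 miRNAs, 21 higher and 25 lower on the high-fat diet, where chance gives 20.4. Of these, 12 also had a fold of at least 1.5, 8 of them higher. The higher and lower counts of unadjusted calls were 93 and 1 without scaling, 20 and 56 with normexp, and 15 and 52 with Agilent's total signal. The 3 values of one diet lay apart from the 3 of the other for 68 miRNAs (16.7%, where chance gives 10%), of which 26 were higher and 42 lower on the high-fat diet. The call of miR-224-3p ended in 4 of the 6 fits that left out 1 array, with adjusted p = 0.0583 without normal chow replicate 2, 0.0996 without normal chow replicate 3, 0.126 without high-fat replicate 2 and 0.0984 without high-fat replicate 3. It held without normal chow replicate 1 (-0.98, adjusted p = 0.0455) and without high-fat replicate 1 (-1.17, 0.0147). The log2 fold change in the 4 fits that lost it lay between -1.10 and -0.9996. The call also ended at similar log2 fold changes in the deposited value table (-1.08, adjusted p = 0.0636), with the slide row as a block, against normal chow replicate 1 alone (-1.22, 0.073), and with no filter on dim miRNAs, where it was -1.06 ± 0.13 (SE, adjusted p = 0.12) and 758 miRNAs were tested. It ended at smaller ones without scaling (-0.70, adjusted p = 0.0946) and with the array's brightness in the fit (-0.80, 0.221). Normexp background correction, whose offset shrinks dim folds by construction, kept the call at -0.50 (0.02).

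Next to miR-224-3p stood 2 miRNAs of higher signal on the high-fat diet that missed the threshold by little. The erythroid miR-144-3p had a log2 fold change of 1.31 ± 0.20 (SE, n = 3 per diet, 2.48-fold, adjusted p = 0.0536). The log2 fold change of miR-141-3p, an epithelial miRNA, was 1.68 ± 0.27 (SE, 3.20-fold, adjusted p = 0.0536). For both, each high-fat array lay above each normal chow array. The next smallest unadjusted p belonged to miR-1949, with a log2 fold change of -0.61 ± 0.11 (SE, adjusted p = 0.0659). Whether miR-144-3p and miR-141-3p counted as called varied with the scaling: both had adjusted p = 0.032 after quantile normalization, and without normal chow replicate 1 that of miR-141-3p was 0.000269 and that of miR-144-3p 0.19. The size varied as well. The log2 fold change of miR-141-3p was 0.77 ± 0.12 (SE) with normexp (adjusted p = 0.0104), whose offset shrinks dim folds by construction. With the slide row as a block, against normal chow replicate 1 alone, it was 0.98. That of miR-144-3p was 0.76 ± 0.12 with the array's brightness in the fit (adjusted p = 0.221).

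**Figure D1:**
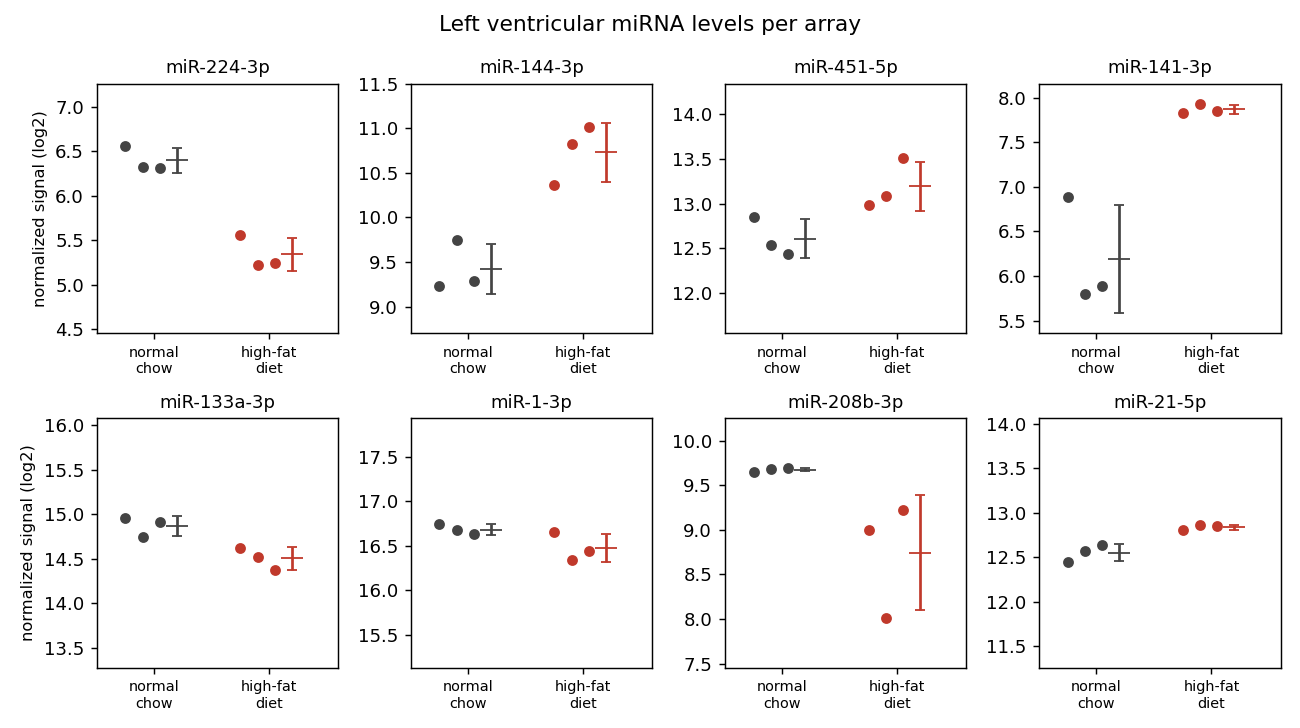
Normalized signal (log2, vertical axis) of 8 miRNAs on each of the 3 normal chow arrays (grey points) and 3 high-fat arrays (red points), with the mean and SD of each diet beside its points. Each panel spans the same log2 range. The high-fat arrays lie below all normal chow arrays for miR-224-3p, the 1 miRNA past the threshold, and above them for miR-144-3p and miR-141-3p, whose adjusted p was 0.0536.

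Muscle miRNAs as a group were lower on the high-fat diet, relative to the other miRNAs. The list holds 9 tested members, 6 of them with a negative log2 fold change, and its median was -0.21 (mean -0.25). The members of the miR-133 family, which are abundant in heart and skeletal muscle, had log2 fold changes of -0.37 ± 0.10 (miR-133a-3p), -0.37 ± 0.08 (miR-133a-5p) and -0.41 ± 0.14 (miR-133b-3p, SE, n = 3 per diet). That of miR-1-3p was -0.21 ± 0.10. Among the miRNAs encoded inside myosin heavy chain genes, miR-208b-3p (Myh7, the slow or fetal ventricular isoform in rodents) had -0.94 ± 0.29, miR-208a-3p (Myh6, the adult isoform) 0.00 ± 0.09 and miR-499-5p (Myh7b) -0.16 ± 0.09. Without high-fat replicate 2 that of miR-208b-3p was -0.57 ± 0.10. The skeletal muscle miR-206-3p had 0.19 ± 0.13, and miR-486 had 0.02 ± 0.15. With camera's preset correlation the list passed (adjusted p = 0.0325 over 21 lists), and with an estimated correlation it did not (adjusted p = 0.483). The estimated correlation was -0.03, below the preset 0.01, so correlation among the members does not account for the lost call. The loss follows from the few residual degrees of freedom that camera uses with an estimated correlation. The unadjusted camera p was 0.0062 with the preset correlation and 0.046 with the estimated one. No member passed over all 408 miRNAs, and 3 were lower adjusted over the list alone, namely miR-133a-3p, miR-133a-5p and miR-208b-3p. The list's call ended after quantile normalization (mean -0.16, adjusted p = 0.231), where miR-1-3p stood at 0.08, with the slide row as a block, against normal chow replicate 1 alone (0.372), with the array's brightness in the fit (0.213), without normal chow replicate 2 (0.0588) or 3 (0.114) and without high-fat replicate 3 (0.0758). Without any scaling, all miRNAs shifted by a median of 0.29, the list's mean was 0.11, below that shift, and miR-1-3p stood at 0.16.

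Erythroid miRNAs as a group were higher on the high-fat diet. Of the list's 4 members, 3 had a positive log2 fold change, and its median was 0.62. Besides miR-144-3p, its cluster partner miR-451-5p, an abundant red cell miRNA processed without Dicer, had a log2 fold change of 0.59 ± 0.17 (SE, n = 3 per diet), and the opposite arm miR-144-5p had 0.64 ± 0.28. For miR-144-5p the diets overlapped, and its log2 fold change was 0.32 ± 0.17 without high-fat replicate 3. It was 0.07 ± 0.11 with normexp, whose offset shrinks dim folds by construction. The fourth member, miR-363-3p, had -0.08 ± 0.09. The list passed with camera's preset correlation (adjusted p = 0.0113) and not with an estimated correlation, which was 0.48 (adjusted p = 0.484). No member passed over all miRNAs, and 2 were higher adjusted over the list alone. The leukocyte list, which marks other blood cells, had a median of 0.08, and in it miR-223-3p, enriched in myeloid cells, had 0.24 ± 0.12 and the lymphocyte miRNA miR-150-5p -0.07. The list's call ended against normal chow replicate 1 alone, a single contrast fitted with the slide row as a block (adjusted p = 0.204) or on row 1 (0.233), with the array's brightness in the fit (0.051) and in the deposited value table (0.0742).

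The epithelial list was higher on the high-fat diet through 2 of its 3 tested members. The log2 fold change of miR-200c-3p, which shares a gene cluster with miR-141-3p, was 0.80 ± 0.18 (SE, n = 3 per diet, adjusted p = 0.109), and it was well above background on 1 of 3 normal chow arrays and 3 of 3 high-fat arrays. The third member, miR-203a-3p, had -0.08 ± 0.12. The other 5 fixed members were not tested, among them miR-200a-3p and miR-200b-3p of the second miR-200 cluster, which normal chow replicate 1 alone detected, and miR-429, which no array detected. A further untested member, miR-205, was detected on high-fat replicates 2 and 3 (6.15 and 4.58, log2 normalized signal) and on normal chow replicate 2 (5.87). The list's median was 0.80, its adjusted p was 0.0156 with the preset correlation and 0.483 with an estimated correlation, and 2 members were higher adjusted over the list alone. The estimated correlation was -0.02, so correlation among the members does not account for the larger p, which follows from the few residual degrees of freedom of that test. The call ended with no filter on dim miRNAs (adjusted p = 0.329), in the deposited value table (0.0984) and with the array's brightness in the fit (0.0539). The size depended on the background correction: with normexp miR-200c-3p stood at 0.02 ± 0.10 (adjusted p = 0.915) and the list's mean at 0.23, against 0.80, with an adjusted p of 0.0456 for the list. Against normal chow replicate 1 alone, the 1 normal chow array that detected it, miR-200c-3p stood at 0.38 and the list's mean at 0.47. It stood at 1.29 with a lower floor, 1.67 with Agilent's total signal and 1.91 in the deposited value table.

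All 5 tested members of the Sfmbt2 cluster, a large group of repeated rodent miRNA genes inside an intron of Sfmbt2, had positive log2 fold changes. As a group they were higher on the high-fat diet, though for some of them another split of the arrays gave larger differences. The list's median was 0.68, with 0.68 ± 0.26 for miR-466b-5p, 0.25 ± 0.16 for miR-466b-3p, 0.42 ± 0.17 for miR-466c-3p and 0.79 ± 0.40 for miR-466c-5p (SE, n = 3 per diet). The list had the smallest adjusted p of the 21, 0.00663 with the preset correlation, and 0.484 with an estimated correlation, which was 0.69. The preset correlation of 0.01 treats these members as nearly independent, and the rank of the list rests on it. No member passed over all miRNAs or adjusted over the list alone, and the diets overlapped for each of these 4. The sequences of this family are near copies of each other, so their probes can share signal. The call ended without normal chow replicate 1 (list mean 0.45, adjusted p = 0.0723) and with the array's brightness in the fit (0.29, 0.15). With normexp the list's mean was 0.22, against 0.58, at an adjusted p of 0.00133, and miR-466c-5p stood at 0.13. The normexp offset shrinks the folds of dim miRNAs by construction. Without high-fat replicate 2 miR-466b-3p stood at 0.11 and miR-466c-3p at 0.26. A different split set normal chow replicate 3 with high-fat replicates 2 and 3 against the other arrays. It gave miR-466c-5p and miR-466d larger log2 differences (1.26 and 1.24) than the diets did (0.79 and 0.78). No other member of the list was called in that split.

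**Figure D2:**
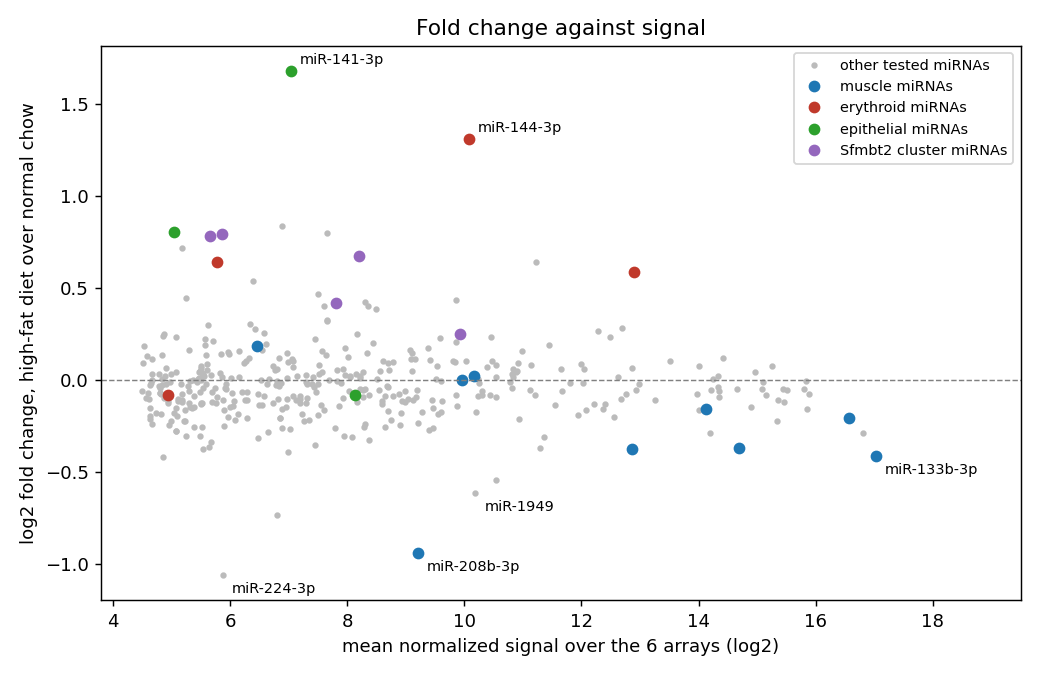
Log2 fold change of high-fat diet over normal chow (vertical axis) against the mean log2 normalized signal over the 6 arrays (horizontal axis) for the 408 tested miRNAs, each a point, with the members of 4 lists in colour. The bright muscle members lie between -0.41 and -0.16, below most other miRNAs of their brightness, and miR-141-3p and miR-144-3p stand highest at 1.68 and 1.31.

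Lists linked to cardiac remodelling did not pass. In the fibrosis-associated list (7 tested members, median 0.10, adjusted p = 0.201), miR-21-5p, abundant in cardiac fibroblasts, had a log2 fold change of 0.29 ± 0.08 (SE, n = 3 per diet, adjusted p = 0.269), and miR-34a-5p, a target of p53, had 0.65 ± 0.16 (adjusted p = 0.16), while miR-125b-5p stood at -0.15 and miR-199a-3p at -0.10. Those 2 first-named miRNAs were higher adjusted over the list alone. The hypertrophy-associated list (14 members, adjusted p = 0.519) had a median of 0.05 and a test direction of up, against a mean of -0.03, with miR-23a-3p at -0.12, miR-22-3p at -0.05 and miR-27b-3p at -0.05. The miR-29 family, which targets collagens, had 3 members between -0.10 and 0.00 (adjusted p = 0.672). All 5 members of the miR-30 family were negative, with a median of -0.13 (adjusted p = 0.277) and -0.22 ± 0.12 for miR-30c-5p. Within the miR-15 family (median 0.06, adjusted p = 0.201) miR-195-5p had 0.11, miR-497-5p 0.23 and miR-16-5p 0.01. The miR-34 family (median 0.15, adjusted p = 0.201) was led by miR-34a-5p, with miR-34b-5p at 0.15 and miR-34c-5p at -0.14.

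Metabolic miRNAs showed no shift past the threshold. The lipid and insulin metabolism list had 13 tested members, 8 of them positive, with a median of 0.05 (adjusted p = 0.3). In it miR-143-3p had 0.05, miR-27a-3p 0.02 and miR-130a-3p -0.11, and the cholesterol regulator miR-33-5p had 0.40 ± 0.18 (SE, n = 3 per diet, adjusted p = 0.443). The brown fat-associated list (3 tested members, median -0.06, adjusted p = 0.762) held miR-193b-3p at -0.36 ± 0.12, miR-365-3p at -0.06 and miR-455-5p at 0.25. Of the liver list only miR-192-5p (0.03) and miR-194-5p (0.03) were tested, too few for a list test, and miR-122-5p, the main hepatocyte miRNA, was not well above background on any array.

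Markers of the other cells of the heart also stayed short of the threshold. The endothelial miR-126a-3p had a log2 fold change of -0.05 ± 0.08 (SE, n = 3 per diet), in a list with a median of 0.05 (adjusted p = 0.519). The smooth muscle list (median 0.08, adjusted p = 0.235) held miR-143-3p at 0.05 and miR-145-5p at -0.04. The leukocyte list had an adjusted p of 0.32, with miR-146a-5p, a miRNA induced by NF-kB, at 0.27 ± 0.09 and miR-142-3p at 0.08. The neuronal list (8 tested members, median 0.02, adjusted p = 0.433) held miR-128-3p at 0.21 and miR-9a-5p at -0.01. Among the broadly expressed families, medians were -0.01 for let-7 (adjusted p = 0.672, test direction up with a mean of -0.00), 0.07 for the miR-17 cluster and its paralogues (0.133), -0.05 for miR-23, miR-24 and miR-27 (0.762) and -0.03 for miR-181 (0.704). The imprinted Dlk1-Dio3 cluster had 18 tested members with a median of -0.08 (adjusted p = 0.519), among them miR-494-3p at -0.15 and miR-493-5p at -0.26.

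**Figure D3:**
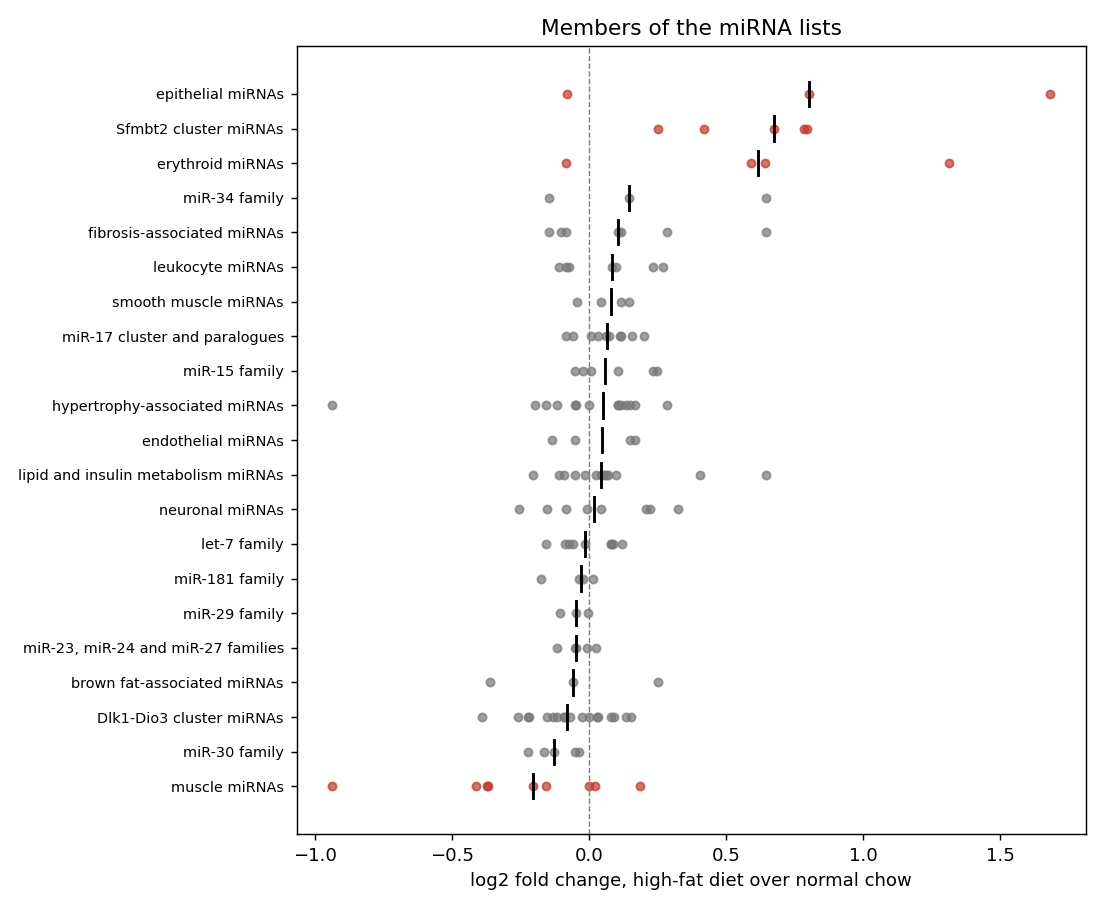
Log2 fold change of high-fat diet over normal chow (horizontal axis) for each tested member (points) of the 21 tested lists (vertical axis), with each list's median as a black bar. Red marks the 4 lists past the threshold with camera's preset correlation, none of which passed with an estimated correlation. That second test has few residual degrees of freedom. The muscle list has the lowest median, -0.21, and the epithelial list the highest, 0.80. The epithelial median is the value of miR-200c-3p, which read the floor on normal chow replicates 2 and 3.

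Other miRNAs were named for their small unadjusted p values. The neighbours miR-532-5p, miR-362-3p, miR-362-5p and miR-500-3p had log2 fold changes of 0.47 ± 0.09, 0.42 ± 0.08, 0.31 ± 0.08 and 0.40 ± 0.12 (SE, n = 3 per diet, adjusted p from 0.0678 to 0.273). Both arms of miR-3084a had negative values, -0.30 ± 0.07 (3p) and -0.37 ± 0.11 (5p). The values were -0.54 ± 0.11 for miR-345-5p, -0.31 ± 0.09 for miR-6328, -0.35 ± 0.10 for miR-6326 and 0.44 ± 0.14 for miR-338-3p. For each of these miRNAs every array of one diet lay on the same side of every array of the other, and none was past an adjusted p of 0.05.

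Detection split completely by diet for 2 miRNAs, both well above background on all 3 high-fat arrays and on no normal chow array. For the passenger strand miR-34a-3p the ratio of the high-fat mean to the normal chow limit was 1.01 (limma, adjusted p = 0.573). As 1 of its probes read the floor on all 6 arrays, this ratio is not a lower bound. For miR-29b-5p the ratio was under 1, so no fold is given. Their signals were near the floor, and the count was 7 when 1 spot sufficed for detection and 6 when all spots were required.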

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

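The tests on the muscle, erythroid and epithelial lists in this part were chosen after the list results were seen. Outside the 408 tested miRNAs, 27 miRNAs were detected on 2 of 3 high-fat arrays and on no normal chow array, and 0 were detected on 2 of 3 normal chow arrays and on no high-fat array. These are detection calls in miRNAs that no comparison above used, most of them at or near the floor. Of the 27, 8 read the floor on all 6 arrays, 13 had a higher and 6 a lower mean on the high-fat diet, with differences from -0.03 to 0.89 log2, so the floor leaves a shift of the set undecided. All but 1 were detected on high-fat replicates 2 and 3, the brightest arrays, whose lowest detected normalized signals were 8.05 and 6.17 against 10.49 to 14.1 on the other 4 arrays. The largest differences, chosen after their values were seen, were those of miR-3596c, miR-3558-3p and miR-207, whose high-fat replicates 2 and 3 read 5.92 and 5.61, 4.93 and 5.93, and 5.57 and 4.72 (log2 normalized signal) against a floor of 4.43 on the other 4 arrays. The set also held miR-224-5p, the opposite arm of the called miRNA, at the floor on all 6 arrays.

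The muscle list was lower on the high-fat diet, with its brightest members at a median log2 fold change of -0.37. If the brightest signals had been compressed on the brighter high-fat arrays, other miRNAs of that brightness would have dropped as far. The 46 other miRNAs of mean log2 signal 12 or more had a median of -0.0493 (95% bootstrap interval -0.0745 to -0.0139). The interval resamples miRNAs and does not carry the spread between arrays. The set leaves out miR-1b, of the miR-1 family and second in brightness, which had -0.28. Its median argues against compression of all such signals as the whole cause. The set was not matched in brightness to miR-133b-3p and miR-1-3p, so compression of the very brightest signals stays open. Quantile normalization, which gives the highest ranks a shared value on each array by its construction, ended the call (list mean -0.25 before and -0.16 after, miR-133b-3p -0.41 ± 0.14 before and -0.07 ± 0.07 after, SE). A smaller share of cardiomyocytes stays open: miR-1-3p and the miR-133 members were lower than miR-208a-3p and miR-499-5p by a difference of -0.26, with a 95% interval from -0.55 to 0.03 that includes 0. An effect of the diet on these miRNAs remains a hypothesis that these 6 arrays did not separate from cell composition or from compression of the brightest signals.

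The erythroid list was higher on the high-fat diet, for which more blood left in the high-fat samples could account, and this would raise miR-144-3p and miR-451-5p alike. The log2 fold change of miR-144-3p exceeded that of miR-451-5p by 0.72, with a 95% interval from -0.01 to 1.45, so a difference in residual blood cannot be told apart from a change in these miRNAs with 3 arrays per diet. The red cell miRNA miR-486 had a log2 fold change of 0.02 (95% interval -0.33 to 0.38), which goes against more blood but does not exclude it, since muscle carries miR-486 too and that level could hide a small share from blood. Array brightness stays open too, since with brightness in the fit the list's mean log2 fold change went from 0.62 to 0.39 and its adjusted p to 0.051, and brightness itself was higher on 2 of the 3 high-fat arrays than on any normal chow array. An effect of the diet was not tested apart from these.

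The epithelial list was higher through miR-141-3p and miR-200c-3p. A single aberrant probe is argued against, as the 2 probes of miR-141-3p gave log2 fold changes of 1.62 and 1.71, a range of 0.0946. Epithelial cells that carry both miR-200 gene clusters would bring miR-200a-3p, miR-200b-3p or miR-429 along, and these had 0 detections in the 9 measurements on high-fat arrays, while normal chow replicate 1 read 5.99 for miR-200a-3p and 6.97 for miR-200b-3p at a lower miR-141-3p signal (6.89) than any high-fat array. Cells that carry the miR-141 and miR-200c cluster alone, handling of the samples and the diet stay open. So does the slide row, which only normal chow replicate 1 shares with the high-fat arrays and which was not tested apart from that array. The background correction stays open too. The normexp values (0.77 for miR-141-3p and 0.02 for miR-200c-3p) cannot decide it, since the normexp offset shrinks dim folds by construction.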

How the results depend on the processing

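Fits with normexp, the slide row and array brightness were chosen after the data were seen. The slide row block and row 1 alone are 1 contrast, normal chow replicate 1 against the high-fat arrays, so they do not test the row. The cause of a change was not tested unless stated. With the main settings 1 miRNA was called (0 higher, 1 lower), and 46 had an unadjusted p under 0.05, 12 of them with a fold of at least 1.5. Across the alternatives the called miRNA and the test directions of the 4 called lists kept their sign in each fit (miR-224-3p from -1.22 to -0.50, adjusted p from 0.0123 to 0.221, past the threshold in 14 of 24). Called miRNAs numbered 7 with normexp (3 higher, 4 lower), 6 after quantile normalization (4 and 2), 4 without scaling (4 and 0), 3 with the 75th percentile over all probes, the median over detected probes, the brightest probe, array weights or detection on all 6 arrays (2 higher in each), 2 with Agilent's total signal (1 higher), and 0, with 0 lower, in the deposited value table, with the slide row as a block, in slide row 1 alone and with array brightness. With no filter the 1 call was miR-3084a-3p (lower). Unadjusted counts were 76 with normexp, 94 without scaling and 23 with array brightness, and those with the fold limit 5 with normexp, 36 without scaling and 7 with no filter. The higher against lower split of the unadjusted calls, 21 and 25 at first, was 93 and 1 without scaling, where the median of all miRNAs moved to 0.29, 20 and 56 with normexp (median -0.10), 15 and 52 with Agilent's total signal (median -0.11), 19 and 49 with the slide row (median -0.10) and 16 and 32 in the deposited table. Leaving out one array each gave 0 to 3 called miRNAs (0 to 2 higher, 0 to 1 lower), 29 to 55 unadjusted and 5 to 19 with the fold limit. The counts were 0 without normal chow replicate 2 or 3 or high-fat replicate 2 or 3. Without high-fat replicate 1 it was 2, and without normal chow replicate 1 it was 3.

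List calls, given as adjusted p with the preset correlation, moved as follows. The muscle list was past the threshold in 13 of 24 alternatives (0.00369 to 0.372), and reached 0.0895 with normexp, 0.231 after quantile normalization, 0.0609 with all probes, 0.0575 with detection on all 6 arrays, 0.218 in the deposited table, 0.372 and 0.362 with slide row as a block and row 1 alone, and 0.213 with array brightness. The erythroid list kept its call in 20 of 24 (0.00143 to 0.233), and lost it in the deposited table (0.0742), with the slide row as a block (0.204), in row 1 alone (0.233) and with brightness (0.051). The epithelial list kept it in 20 of 23 (0.00085 to 0.329), and lost it with no filter (0.329), in the deposited table (0.0984) and with brightness (0.0539). With detection on all 6 arrays it had too few members. The Sfmbt2 cluster kept it in 22 of 24 (4.25e-05 to 0.15), with 0.15 under brightness. With normexp the fibrosis list (0.00669), let-7 (0.0217), miR-15 (0.00481), the miR-17 cluster (0.00669), the lipid list (0.00864) and the leukocyte list (0.0321) passed as well. So did smooth muscle with Agilent's total signal (0.0178), no filter (0.0107) and the deposited table (0.0405), and the miR-17 cluster with no filter (0.00593). Leaving out one array gave 0.025 to 0.114 for the muscle list (past 0.05 without normal chow replicate 2 or 3 or high-fat replicate 3) and 4.25e-05 to 0.0723 for the Sfmbt2 cluster (0.0723 without normal chow replicate 1). It gave 0.033 to 0.505 for the miR-15 family and 0.033 to 0.587 for the miR-34 family, both passing without high-fat replicate 2. No list passed with an estimated correlation in any fit. The few residual degrees of freedom of that test make passing hard for any list, so this does not single out correlation among members.

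The replicate number as a block gave 2 called miRNAs (miR-144-3p, 1 higher, and miR-224-3p), and the same side of the threshold for each list. The deviations of same-numbered arrays from their group means correlated at 0.23, -0.14 and 0.03, so the numbers were not taken as pairs. The planned slide or scan block was not run, since all arrays carry 1 scan identifier. Detection split completely by diet for 7 miRNAs when 1 spot sufficed and for 6 when all spots were required. Signal over background limits the dim miRNAs, since 15% to 23.2% of miRNA spots per array were negative after background subtraction.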

Other observations

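The tests of arms, gene neighbours and the other splits' members in this part were chosen after part of the fold changes had been seen. Gene neighbours of the X-linked miR-532 to miR-500 group, which lies inside Clcn5, formed a set of 9 tested miRNAs from 6 genes within 10 kb of each other in assembly GRCr8 order. Their mean log2 fold change on the high-fat diet was 0.21, 6 of 9 were positive, and 4 had an unadjusted p under 0.05. Camera gave an adjusted p of 0.00214 over the 32 gene clusters with at least 3 tested miRNAs, and 0.888 with an estimated correlation, a test on few residual degrees of freedom. In the same test the cluster of miR-144 and miR-451 had a mean of 0.85 (adjusted p = 0.00133, and 0.788 with an estimated correlation), and the miR-1 and miR-133a cluster had -0.24 (0.0662). The neighbouring genes of miR-206 and miR-133b gave 3 tested miRNAs with a mean of -0.15 (0.978).

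A hypothesis that neighbouring genes share a primary transcript predicts that their fold changes go together. Over 221 pairs of neighbouring genes the mean product of standardized log2 fold changes was 0.23. This lay above the 95% range of shuffled genes (-0.12 to 0.14, one-sided permutation p = 0.0054), as shared transcripts predict. Without the pair of miR-141 and miR-200c it was 0.12 (one-sided permutation p = 0.04). That value lies inside the 95% range given for all 221 pairs, while its own one-sided p stays under 0.05, so the result leans in large part on this pair. Many of the pairs came from 1 cluster of 16 genes. The other 9 splits of the 6 arrays gave 0.02 to 0.35, so the agreement belongs to differences between samples in general and does not speak for the diet.

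The 2 arms of 1 precursor also went together across 94 precursors with both arms tested, which are not independent replicates. Pearson's r was 0.52 (permutation p = 1e-05, the smallest that 100000 permutations give) and Spearman's rho 0.35 (permutation p = 8e-04), against a range of -0.20 to 0.22 for shuffled pairs. Without miR-466c and miR-3573, the 2 precursors whose 5p arm lay farthest from the median, r was 0.49. That check kept miR-144, whose arms stood at 0.64 (5p) and 1.31 (3p). Spot-level hybridization noise alone would leave r inside that range. In 59 of the 94 the arms had the same sign. The other splits of the arrays gave r from -0.10 to 0.46.

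The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split had 1 called miRNA, and 2 of the 10 splits had as many, the highest other count being 6. For called higher miRNAs the real count was 0, which every split reaches by definition, so this comparison decides nothing (highest other 6). For called lower ones the real count of 1 was reached in 2 of 10 (highest other 6, counting each split with its mirror). For unadjusted calls the real count of 46 was reached in 1 split (highest other 32), with the fold limit 12 in 1 split (highest other 9), and for lists past the threshold 4 in 1 split (highest other 3). The split with 6 calls set normal chow replicate 3 with high-fat replicates 2 and 3. Differences between samples apart from the diet may underlie these calls, which was not tested, and that split had fewer unadjusted calls than the diets (28 against 46), fewer with the fold limit (9 against 12) and fewer lists (1 against 4). Its calls were miR-3588, miR-465-5p, miR-466c-5p, miR-466d, miR-483-3p and miR-672-5p, chosen after their values were seen, of which 2 are members of the Sfmbt2 cluster list. Those 2 differed by 1.26 (miR-466c-5p) and 1.24 (miR-466d) on the log2 scale in that split, against 0.79 and 0.78 between the diets. In normal chow replicate 3 miR-466c-5p read 6.15, against 5.13 and 5.08 in replicates 1 and 2, and in the high-fat replicates it read 5.46, 6.70 and 6.59.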
